A study of Homo sapiens with 6 samples.

How the data were processed

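RNA was measured in 6 libraries of SNU449 cells, an established human hepatocellular carcinoma line. Per the labels, the cells had been transfected for 48 h with a control small interfering RNA (siControl, 3 libraries) or with one against the oxytocin receptor gene (siOXTR, 3 libraries), lysed in Trizol, and made into libraries by the BGISEQ-500 protocol. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures. The p-values of single genes below therefore measure only the spread between these libraries, which may be technical. The siRNA sequences, and whether siOXTR was a single siRNA or a pool, are not given in the sources used here.

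The deposited values are FPKM (fragments mapped to a gene, scaled to its length and to the total of mapped fragments), per the file headers, with 1 row for each of 17153 genes named by NCBI gene ID and symbol and 2 decimals per value. The authors scaled each value to gene length and library size, as the unit implies, so the values carry no read counts. The aligner, the counting tool, the genome build, the annotation and any filter are not given in the sources used here, nor is the way reads shared by near-identical genes were assigned. Levels of ribosomal protein, actin and ferritin genes, which have many processed pseudogenes, are uncertain to that extent.

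The depth of each library is unknown. For genes of low level, the values were compared with whole multiples of a gene's lowest step. Of 119 values from 92 genes, 22.7% lay within 0.1 of a whole multiple, against 20% by chance, so whole reads were not recovered and no count model was used. The precision is described by the spread between libraries instead, and a gene listed at 0 is reported as listed at 0.

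The test had been fixed for either kind of unit before the data were examined, and the form for FPKM applied. Values were transformed as log2(FPKM + 1), and the 11655 genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested with limma 3.58.1 (R 4.3.3), group as the single factor, with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. A log2 change is the difference of the group means on this scale and understates the change of genes of low level. Fold values are ratios of the mean FPKM of the groups. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so no such p is given.

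Gene lists were written before the data were examined: 25 lists with 698 entries, of which 671 were in the files. The 23 lists with at least 5 tested members were compared with the remaining genes by camera (limma) with a preset correlation between genes of 0.01, and adjusted over those lists. Camera with a correlation estimated for each list (statmod 1.5.0) and fry, which asks whether a list's own genes move in 1 direction on balance, were alternatives.

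The genes named in the text were chosen by a rule written before the data were examined. It takes OXTR, then the 12 largest increases and the 12 largest decreases in log2 change among genes past the threshold, with no overlap between the groups, a mean of at least 5 FPKM over the 6 libraries and an established symbol. It then takes the 4 members with the smallest adjusted p in each list that passed camera or had at least 3 members past the threshold, and the measured members of the oxytocin and vasopressin receptor family with the OXT gene. Members named because they went against their list, and any gene said to be chosen after its values were seen, lie outside that rule. Some genes that it takes are not reported here.

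Alternatives set beforehand were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at 5 FPKM, quantile and median-ratio scaling, robust empirical Bayes, the replicate number as a block, and leaving out each library in turn. Removal of a loess trend (span 0.5) on transcript length and GC content from each library was added after the data were seen. Transcript length, GC content, 3' UTRs and encoded proteins came from the longest principal protein-coding transcript per gene in GENCODE release 29, matched by NCBI gene ID for 99.5% of the genes tested. This annotation was used for these properties alone, and no genomic coordinates are given because the authors' build is not named.

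For the closing section, the log2 change of 11326 genes with a 3' UTR of at least 50 bases was adjusted by regression for UTR length, UTR GC content and mean level. The mean of the genes carrying each of 16144 words of 7 bases, each present in at least 50 genes, was then scored against 1000 permutations of the changes. Since the siRNA sequences are not known, each of the 4096 cores of 6 bases was also tested. The share of the lower genes that a core accounts for is the excess of carriers over other genes in the same 10 bins of UTR length, divided by the share expected to lack the core. The class difference was taken among genes without the core. The permutation p-values and intervals of the closing section compare genes with other genes and do not measure the spread between libraries. They treat genes as independent units, which genes that change together are not, so they may overstate the evidence. Proteins were assigned a predicted signal or membrane segment where 11 residues starting within the first 25 had a mean hydropathy of at least 2.0, or where 19 residues after residue 40 reached 1.8. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

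The tests were also run on simulated data. With changes planted in simulated values for the comparison of siOXTR with siControl (11573 genes tested), limma recovered 24 of 50 genes raised by 0.25 on the log2 scale, 24 of 50 lowered by 0.25, 46 of 50 raised by 0.5 and 50 of 50 raised by 1, and called 4 unchanged genes. Camera called a planted list of 30 genes raised by 0.3 and 0 of 40 unmoved lists. In the simulated values genes varied independently and only planted genes moved, whereas 82.5% of the genes tested passed the threshold in the data. The recovery by limma and the result for camera may therefore not carry over to the genes and lists tested here. The word scan recovered 3 of 10 words carried by between 800 and 2000 genes and planted at -0.09. The number of carriers was then narrowed to between 1500 and 1900, close to the 1692 of the strongest word, after that result was seen. In that range, 18 of 20 words planted at -0.09 and 20 of 20 planted at -0.18 were recovered, so the scan can miss words of this effect size that fewer genes carry.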

Results

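The data set held mRNA profiles of SNU449 cells 48 h after transfection with a control siRNA (siControl, n = 3 libraries) or with an siRNA against OXTR (siOXTR, n = 3 libraries). An siRNA is a short double-stranded RNA that directs the cleavage of mRNAs with a matching sequence. OXTR (NCBI gene ID 5021) encodes the oxytocin receptor, a receptor coupled to Gq proteins. The series title places the comparison in a study of what this receptor does in the formation of hepatocellular carcinoma. FPKM values were given for 17153 genes in each library. They summed to between 412464 and 415902 in the siControl libraries and to between 424168 and 429456 in the siOXTR libraries, and between 1286 and 1458 genes per library were listed at 0. The 10 genes with the highest FPKM took 6.34% to 6.41% of the total in the siControl libraries and 7.49% to 7.58% in the siOXTR libraries. The most abundant transcript was that of ACTB or TMSB4X in the siControl libraries and that of FTL in the siOXTR libraries. Across the genes tested, which are not independent replicates, Pearson correlations of log2 values were between 0.997 and 0.998 within a group and between 0.922 and 0.923 across the groups. The median SD between libraries of 1 group was 0.05 on the log2 scale in siControl and 0.05 in siOXTR.

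The targeted transcript was lower in every siOXTR library. OXTR was at 26.5, 26.6 and 24.6 FPKM in the siControl libraries and at 6.03, 6.11 and 6.14 FPKM in the siOXTR libraries. The means were 25.9 ± 1.13 FPKM (SD, n = 3) and 6.09 ± 0.0569 FPKM (SD, n = 3), a 4.24-fold lower level. The log2 change was -1.92 (SE 0.04, limma adjusted p = 3.45e-11). The related vasopressin receptor gene AVPR1A was near the floor, at 0.293 ± 0.0651 FPKM in siControl and 0.0667 ± 0.0321 in siOXTR, as were AVPR2 and the oxytocin gene OXT, so none of these was tested. The mean FPKM of OXT was 0.04 in siControl and 0.0667 in siOXTR, and AVPR2 was listed at 0 in all siControl libraries. AVPR1B was not analysed here.

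Knockdown of OXTR was accompanied by expression changes across most of the measured transcriptome. By the rule for named genes, the largest increase was in the stress-response gene DDIT3 (log2 change 4.34) and the largest decrease in the matricellular gene CCN2 (log2 change -4.68). Of 11655 genes tested, 9613 passed the threshold (82.5%), with 4395 higher and 5218 lower in siOXTR. Most changes were small: 549 genes were higher and 797 lower by at least 1 on the log2 scale. These counts depend on the pseudocount, with 712 and 1102 at a pseudocount of 0.1 and 740 and 1148 at 0.01. The libraries of the groups did not overlap in 9669 genes (83.0%), where chance gives 10%. The median log2 change of all genes tested was -0.06. Under quantile scaling it was 0.003, with 4801 genes higher and 4714 lower, so the excess of lower genes depends on the scaling.

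Among the 12 largest increases, DDIT3, which encodes the stress-induced transcription factor CHOP, rose 21.9-fold to 262 ± 13.2 FPKM (log2 change 4.34, SE 0.04, adjusted p = 2.40e-13). PPP1R15A, which encodes the phosphatase subunit GADD34 that reverses stress-induced translational arrest, rose 12.7-fold (log2 change 3.62). GDF15, a secreted stress cytokine, rose from 156 ± 4.96 to 1877 ± 25.9 FPKM. The stress-responsive transcription factor gene ATF3 rose 13.4-fold, the pseudokinase gene TRIB3 10.2-fold, the sestrin gene SESN2 12.1-fold, and HERPUD1, which acts in the degradation of endoplasmic reticulum proteins, 10.2-fold. HKDC1, a gene of the hexokinase family, rose 12.4-fold, and RND3 had a log2 change of 3.39. The log2 change was 3.26 for LURAP1L and 3.25 for MSC, which encodes the transcription factor musculin. OLAH, which encodes a thioesterase that releases medium-chain fatty acids, rose from 0.837 ± 0.120 to 19.6 ± 0.235 FPKM.

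Among the 12 largest decreases, CCN2, which encodes a matricellular growth factor, fell from 81.0 ± 2.72 to 2.21 ± 0.0950 FPKM (log2 change -4.68, SE 0.04, adjusted p = 1.41e-13). The chemokine gene CCL2 fell from 14.2 ± 0.875 to 0.147 ± 0.124 FPKM, a level at which a fold is imprecise. Of genes for secreted or matrix proteins, THBS1 (thrombospondin) was 15.5-fold lower, VCAN (versican) 7.81-fold lower and FGB (the fibrinogen beta chain) 11.9-fold lower. The adhesion and junction genes CADM1 and CLDN2 were 12.2-fold and 15.2-fold lower. ADAM9, which encodes a membrane-bound metalloprotease, fell from 198 ± 5.05 to 26.2 ± 0.401 FPKM. NREP was 10.4-fold lower. The log2 change was -2.81 for CALD1, which encodes the actin-binding protein caldesmon, and -2.76 for the interferon-inducible GTPase gene GBP1. The groups did not overlap in any of the genes given here, which the rule required.

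**Figure D1:**
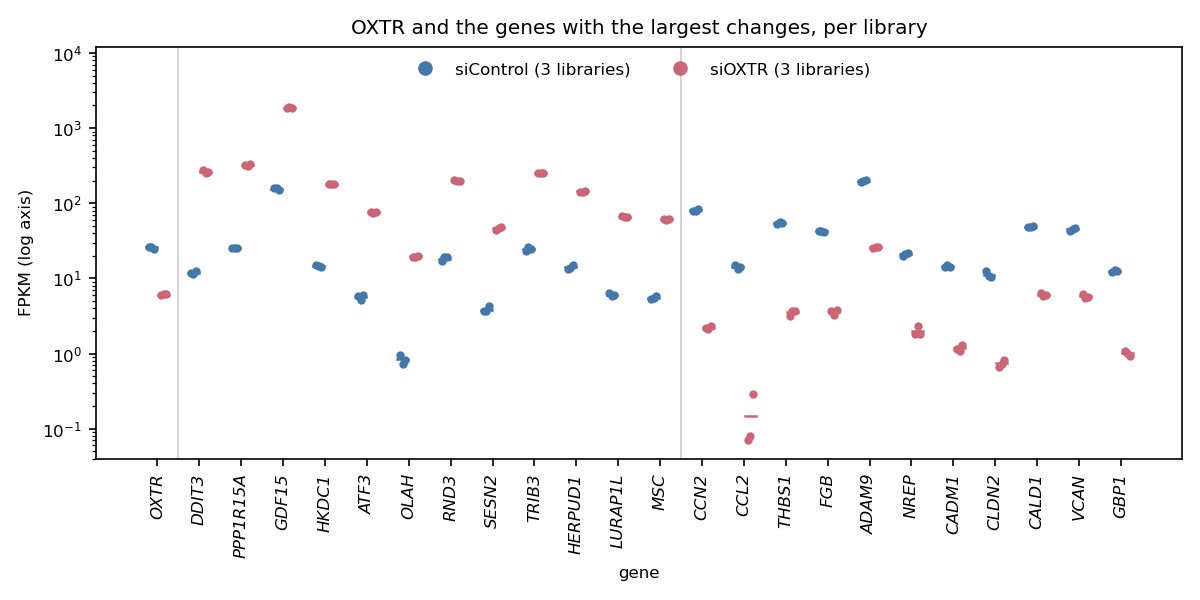
FPKM of OXTR, of the 12 genes with the largest increase and of 11 of the 12 with the largest decrease (x axis) on a log axis (y axis), with 1 point per library and a bar at each group mean (n = 3 libraries per group, blue for siControl and red for siOXTR). The points of the groups do not overlap in any gene shown, which the rule required of all but OXTR. OXTR lies at 25.9 FPKM on average in siControl and 6.09 FPKM in siOXTR.

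**Figure D2:**
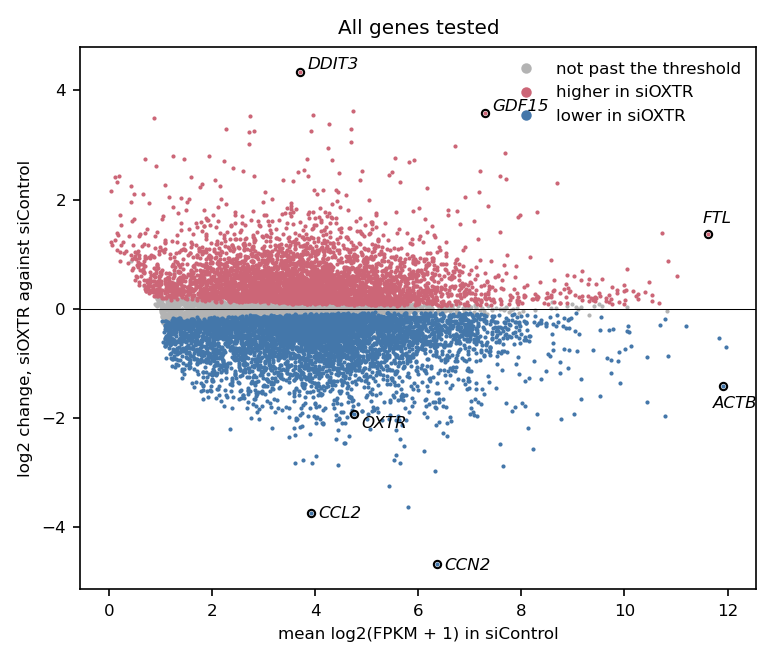
Log2 change, siOXTR against siControl (y axis), against the mean log2(FPKM + 1) of the 3 siControl libraries (x axis), with 1 point for each of the 11655 genes tested. Red points are the 4395 genes past the threshold and higher in siOXTR, blue points the 5218 past it and lower, and grey points did not pass. OXTR has a log2 change of -1.92, DDIT3 of 4.34, GDF15 of 3.58, CCN2 of -4.68 and CCL2 of -3.73. The abundant genes FTL (1.38) and ACTB (-1.41) were labelled after their values were seen.

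Of the 23 gene lists tested with camera, 15 differed from the remaining genes at an adjusted p under the threshold. With the correlation between genes estimated for each list, 3 did: DNA replication and G1/S, cholesterol synthesis, and immediate early genes. Members are counted as having risen or fallen where they passed the threshold over all genes tested. The counts adjusted over the list alone were the same except in the 2 lists where both are given. Some genes belong to more than 1 list, so the lists are not independent of each other.

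Genes of the unfolded protein and integrated stress response, which limits protein synthesis and raises chaperones and amino acid supply, moved mostly upward. Of 28 members tested, 22 rose and 6 fell (median log2 change 1.66, camera adjusted p = 2.48e-06, and adjusted p = 0.119 with an estimated correlation). The 4 members with the smallest adjusted p were PPP1R15A, DDIT3, TRIB3 and HERPUD1, given above. Of members chosen after their values were seen, ATF4, the central transcription factor of the integrated stress response, had a log2 change of 2.05, the endoplasmic reticulum chaperone gene HSPA5 of 1.71 and XBP1 of 1.75. The 6 that fell were VLDLR (-0.76), EDEM1 (-0.51), SEL1L (-0.39), PDIA4 (-0.35), PDIA6 (-0.25) and HSP90B1 (-0.12), of which PDIA4, PDIA6 and HSP90B1 encode folding enzymes and chaperones of the endoplasmic reticulum and SEL1L and EDEM1 act in the degradation of its proteins. Immediate early genes, which are transcribed within minutes of a stimulus, rose in 18 of 20 cases (median log2 change 0.86, camera adjusted p = 2.48e-06, and adjusted p = 0.0395 with an estimated correlation). KLF6 rose from 42.1 ± 0.427 to 233 ± 3.30 FPKM, IER3 rose 5.21-fold and JUN 2.66-fold, beside ATF3. EGR1 (-0.66) and MCL1 (-0.10) fell.

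Cell cycle genes were lower in siOXTR. In the list of DNA replication and the G1/S transition, 33 of 36 members fell and 1 rose (median log2 change -0.97, camera adjusted p = 2.73e-07, and adjusted p = 0.0395 with an estimated correlation). Of genes for the replicative helicase, MCM6 fell from 76.7 ± 1.67 to 22.8 ± 0.157 FPKM, MCM3 was 3.92-fold lower and MCM4 3.29-fold lower. The member that rose was GINS3 (0.37). In the list of mitosis and G2/M, 33 of 36 members fell and 1, CENPA (0.33), rose (median log2 change -0.58, camera adjusted p = 2.48e-06, and adjusted p = 0.0643 with an estimated correlation). The topoisomerase gene TOP2A fell from 136 ± 1.65 to 42.6 ± 1.40 FPKM, and ANLN, KIF11 and CDK1, which act in cytokinesis, spindle assembly and mitotic entry, were 2.22-fold, 2.24-fold and 1.91-fold lower.

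Lipid synthesis genes were lower as well. All 24 members of the cholesterol synthesis list fell (median log2 change -0.88, camera adjusted p = 3.67e-07, and adjusted p = 0.0395 with an estimated correlation). IDI1, which encodes an isomerase of the isoprenoid part of the pathway, fell from 134 ± 4.85 to 34.2 ± 0.887 FPKM and was 3.91-fold lower. In the fatty acid synthesis list 14 of 18 members fell and 2 rose (median log2 change -0.85, camera adjusted p = 0.00306, and adjusted p = 0.119 with an estimated correlation). The stearoyl-CoA desaturase gene SCD fell from 258 ± 3.76 to 77.0 ± 0.564 FPKM, and FASN, ACSL3 and FADS2 were 2.77-fold, 2.86-fold and 3.97-fold lower. ME1 (1.18) and AGPAT2 (0.13) rose.

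In the list of hypoxia and glycolysis, 21 of 25 members fell and 4 rose (median log2 change -0.79, camera adjusted p = 4.47e-04, and adjusted p = 0.128 with an estimated correlation). LDHA, the lactate dehydrogenase A gene, fell from 1772 ± 19.8 to 453 ± 6.48 FPKM. The glycolytic genes PGAM1 and TPI1 were 3.02-fold and 2.25-fold lower, and the collagen prolyl hydroxylase gene P4HA1 was 3.70-fold lower. VEGFA (1.17), HK2 (0.99), NDRG1 (0.84) and KDM3A (0.12) rose. Of 40 oxidative phosphorylation genes, 34 fell and 2 rose, mostly by small amounts (median log2 change -0.32, camera adjusted p = 3.84e-04, and adjusted p = 0.235 with an estimated correlation). The complex I gene NDUFB3 was 2.21-fold lower, NDUFA2 1.92-fold lower and the complex II gene SDHD 1.54-fold lower, whereas SDHB, of the 2 that rose, had a log2 change of 0.33. Cytosolic ribosomal protein genes moved slightly upward. Of 47 tested, 40 rose and 1, RPL22 (-0.10), fell, or 41 and 2 when adjusted over the list alone (median log2 change 0.20, or 0.11 under quantile and 0.26 under median-ratio scaling, camera adjusted p = 1.46e-05, and adjusted p = 0.245 with an estimated correlation). RPL12 rose from 755 ± 20.9 to 1098 ± 26.0 FPKM, and RPL10, RPL10A and RPS6 rose 1.44-fold, 1.30-fold and 1.24-fold.

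**Figure D3:**
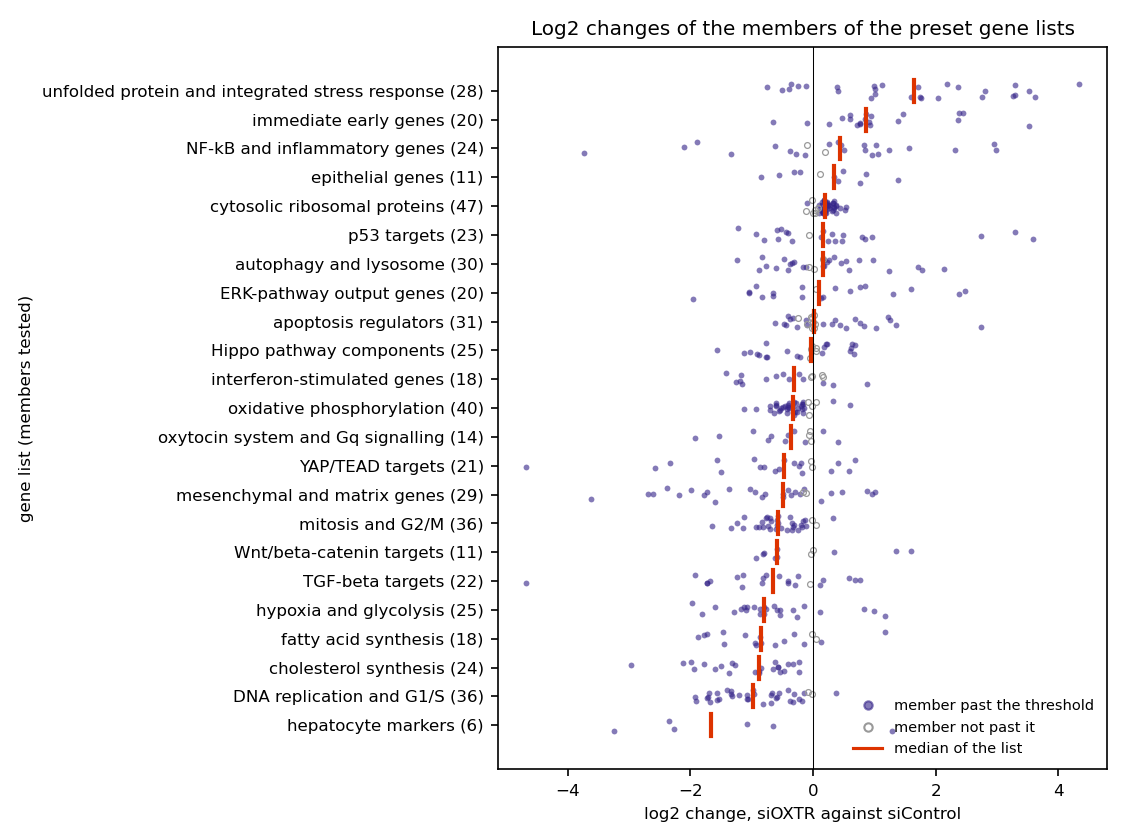
Log2 change, siOXTR against siControl (x axis), of the tested members of each of the 23 gene lists (y axis, with the number of members tested in parentheses), ordered by the median of the list. Each point is 1 gene, filled where it passed the threshold and open where it did not, and each red bar is the median of the list. The medians run from -1.67 for hepatocyte markers to 1.66 for the unfolded protein and integrated stress response, and that of the Hippo pathway components (-0.03) changes sign under the other scalings of the libraries.

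Matrix genes and the targets of pathways that regulate them were mostly lower. Of 29 mesenchymal and matrix genes, 21 fell and 6 rose (median log2 change -0.49, camera adjusted p = 0.00305, and adjusted p = 0.146 with an estimated correlation). LOXL2, which encodes a collagen-crosslinking oxidase, fell from 279 ± 4.15 to 60.7 ± 1.39 FPKM, and the collagen gene COL1A2 and SPARC were 4.07-fold and 6.55-fold lower, beside THBS1. The 6 that rose were ZEB2 (1.01), SNAI1 (0.96), VIM (0.89), ZEB1 (0.48), LOX (0.30) and CD44 (0.13), of which ZEB1, ZEB2 and SNAI1 encode transcription factors that repress epithelial genes. Of 22 TGF-beta targets, 16 fell and 5 rose (median log2 change -0.66, camera adjusted p = 0.0102, and adjusted p = 0.119 with an estimated correlation). The tropomyosin gene TPM1 was 3.84-fold lower, and TGFBI was 3.38-fold lower, beside CCN2. JUNB (0.77), SKIL (0.69), BAMBI (0.58), ID2 (0.16) and BHLHE40 (0.11) rose.

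Of 21 targets of the transcriptional co-activator YAP and its TEAD partners, 15 fell and 4 rose (median log2 change -0.47, camera adjusted p = 0.0177, and adjusted p = 0.128 with an estimated correlation). CCN1 fell from 297 ± 2.65 to 49.0 ± 0.352 FPKM, and CRIM1 and the receptor tyrosine kinase gene AXL were 5.27-fold and 2.89-fold lower, beside CCN2. ANKRD1 (0.69), GADD45A (0.59), RBMS3 (0.42) and TGFB2 (0.29) rose. CCN2 counts in both this list and the TGF-beta list. The components of the Hippo pathway, which restrains YAP, went both ways: 9 of 25 rose and 11 fell (median log2 change -0.03, camera adjusted p = 0.614, and adjusted p = 0.799 with an estimated correlation), and the median was 0.02 under quantile and 0.03 under median-ratio scaling. AMOTL2 was 3.14-fold lower, WWTR1, which encodes the YAP paralog TAZ, 1.95-fold lower and MOB1A 1.73-fold lower, and TEAD1 had a log2 change of -0.89. YAP1, chosen after its value was seen, had a log2 change of 0.05 that did not pass the threshold (adjusted p = 0.292).

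Of 14 genes of the oxytocin system and Gq signalling, 9 fell and 2 rose, OXTR included (median log2 change -0.36, camera adjusted p = 0.0493, and adjusted p = 0.235 with an estimated correlation). OXTR (log2 change -1.92) was the target of the siRNA, so its fall was set by the experiment, and the list was not tested without it. LNPEP, which encodes an aminopeptidase that degrades oxytocin, fell from 10.2 ± 0.330 to 2.87 ± 0.110 FPKM, the phospholipase C gene PLCB4 was 1.71-fold lower and the calcium-release channel gene ITPR1 2.96-fold lower. GNAQ, which encodes a Gq subunit, had a log2 change of 0.40 and ITPR3 of 0.17. The list also missed the threshold under 7 other settings, with an adjusted p from 0.0564 without siOXTR library 1 to 0.164 with a filter at 5 FPKM. Genes driven by the ERK pathway went both ways, with 10 of 20 higher and 9 lower (median log2 change 0.10, camera adjusted p = 0.423). IER3, the phosphatase gene DUSP5 and MYC rose 5.21-fold, 5.79-fold and 3.09-fold, whereas the receptor gene EPHA2 was 4.11-fold lower. Of 11 Wnt/beta-catenin targets, 3 rose and 6 fell (median log2 change -0.59, camera adjusted p = 0.489). MYC and the Wnt antagonist gene DKK1 rose 3.09-fold and 2.57-fold, and NKD2 had a log2 change of 0.35, whereas the cyclin D1 gene CCND1 and ZNRF3 were 1.92-fold and 1.97-fold lower.

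Of 24 NF-kB and inflammatory genes, 14 rose and 8 fell, or 15 and 8 when adjusted over the list alone (median log2 change 0.44, camera adjusted p = 0.0496, and adjusted p = 0.160 with an estimated correlation). The chemokine genes CXCL8 and CXCL2 rose 7.96-fold and 8.07-fold, CXCL8 from 104 ± 2.17 to 824 ± 6.94 FPKM, and the cytokine gene IL6 rose 5.05-fold. The adhesion molecule gene ICAM1 was 3.79-fold lower, and CCL2, given above, fell. The list also missed the threshold under 8 other settings, with an adjusted p from 0.0501 with a filter at 5 FPKM to 0.0843 with the length and GC trend removed, a setting chosen after the data were seen. Of 18 interferon-stimulated genes, 11 fell and 3 rose (median log2 change -0.31, camera adjusted p = 0.161). OAS3, OAS1 and IFI6 were 2.81-fold, 2.58-fold and 2.55-fold lower, whereas IRF9 rose 1.93-fold, and HERC5 (0.33) and STAT2 (0.16) rose too.

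Lists of p53 targets, apoptosis regulators and autophagy genes held large changes in single members and did not differ from the remaining genes. Of 23 p53 targets, 13 rose and 9 fell (median log2 change 0.17, camera adjusted p = 0.278). Beside GDF15 and SESN2, the pro-apoptotic gene BBC3 rose from 1.73 ± 0.201 to 17.2 ± 0.580 FPKM and PHLDA3 rose 1.99-fold. CDKN1A, a classical p53 target chosen after its value was seen, had a log2 change of -0.07 that did not pass the threshold (adjusted p = 0.0796). Of 31 apoptosis regulators, 13 rose and 9 fell (median log2 change 0.01, camera adjusted p = 0.161). BMF, which promotes apoptosis, rose 2.56-fold, and BCL2L1, best known for its anti-apoptotic product, rose 1.72-fold. Of 30 autophagy and lysosome genes, 15 rose and 12 fell (median log2 change 0.16, camera adjusted p = 0.387). The autophagosome genes MAP1LC3B, WIPI1 and SQSTM1 rose 3.31-fold, 4.56-fold and 3.43-fold.

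Of 30 hepatocyte markers, 25 were in the files and 6 of these were expressed highly enough to be tested, of which 5 fell (median log2 change -1.67, camera adjusted p = 0.0494, and adjusted p = 0.235 with an estimated correlation). The fibrinogen genes FGG and FGA were 5.03-fold and 8.30-fold lower, beside FGB, the urea cycle gene CPS1 was 2.35-fold lower and FOXA1 had a log2 change of -0.65, whereas FOXA2 rose (1.28). The list also missed the threshold under 6 other settings, with an adjusted p from 0.0539 with a pseudocount of 0.1 to 0.312 without the filter on low values. Of 11 epithelial genes, 6 rose and 4 fell (median log2 change 0.35, camera adjusted p = 0.201). The keratin gene KRT18 and the desmosomal gene DSP rose 1.41-fold and 1.94-fold, ESRP1 rose from 0.107 ± 0.0153 to 1.91 ± 0.136 FPKM, whereas JUP was 1.88-fold lower and KRT7 (-0.55), LSR (-0.31) and CLDN3 (-0.22) fell. Of 23 leukocyte markers, 14 were in the files and 3 of these were tested: CD68 rose from 5.99 ± 0.490 to 10.7 ± 1.02 FPKM, CORO1A fell from 3.88 ± 0.246 to 0.603 ± 0.116, and LCP1 fell from 2.20 ± 0.166 to 1.70 ± 0.0666, a change that did not pass the threshold under quantile scaling (adjusted p = 0.263). Of 17 endothelial markers, 14 were in the files and 1 of these was tested, EGFL7, which fell from 11.6 ± 1.24 to 9.36 ± 0.583 FPKM. Lists with fewer than 5 tested members were not compared by camera.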

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

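The removal of the length and GC trend was chosen after the data were seen, and the other settings before. The number of genes past the threshold stayed within 1.5 times of 9613 under each setting tried, from 8044 with a filter at 5 FPKM to 10361 with no filter on low values, and from 9113 to 9253 with 1 library left out. OXTR stayed lower and past the threshold, with log2 changes from -2.08 with a pseudocount of 0.01 to -1.85 with the trend removed. Quantile scaling gave 4801 genes higher and 4714 lower, and median-ratio scaling 4797 and 4763, against 4395 and 5218. Of the values of the single genes that the rule takes under these settings, 1525 kept their direction and side of the threshold and 1 did not: LCP1 under quantile scaling (log2 change -0.09, adjusted p = 0.263). None of these genes reversed, nor did the direction that camera or fry gave for any list, although the median of the Hippo pathway list changed sign under quantile and median-ratio scaling. The median was 0.20 and became 0.11 under quantile scaling for cytosolic ribosomal proteins, and under median-ratio scaling it rose from 0.10 to 0.16 for ERK-pathway genes and from 0.01 to 0.07 for apoptosis regulators. The number of lists past the threshold fell from 15 to 3 with camera and an estimated correlation, and was 22 with fry, which does not compare a list with other genes. The camera adjusted p also rose where the estimated correlation was below the preset 0.01. It went from 2.73e-07 to 0.0395 for DNA replication and G1/S (correlation -0.015) and from 3.67e-07 to 0.0395 for cholesterol synthesis (-0.028). A higher correlation was thus not the reason in those lists. The preset and estimated forms of camera therefore differ in more than the value of the correlation. In other lists, such as oxidative phosphorylation (0.15), the estimate was above the preset value, but the rise cannot be put down to it alone. Over all settings, 351 list results were the same, 33 missed the threshold and 7 passed it anew, all 7 with fry. Apart from the estimated correlation, the lists that missed it were those of oxytocin and Gq signalling, hepatocyte markers, and NF-kB and inflammatory genes, which lay between 0.0493 and 0.0496 at first. The cause was not tested.

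With the replicate number as a block (replicate block), 9593 genes passed, 12 lists did, and OXTR kept its log2 change of -1.92. The deviations of same-numbered libraries correlated at -0.012, -0.073 and 0.039, and 1 of 6 libraries correlated best with the one of its own number. No pairing by number was thus seen, which does not settle whether same-numbered libraries shared a culture or a batch. The alternatives planned for read counts (DESeq2, library-size scaling, no count filter) were not run because the values are FPKM. The depth is unknown, so what it limits cannot be stated, and differences between genes near 0 FPKM rest on few decimals.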

Other observations

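In this part, the gene groups of the next 2 paragraphs were chosen after the values were seen. So were the tests for abundant genes, for chance over all words, for base composition and for the length and GC trend. The words used in the match tests were picked from the values as well. The tests over all 6-base cores were added after those of the single words.

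Further groups moved together. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 16 rose and 1, FARSA (-0.31), fell (median log2 change 0.65, camera adjusted p = 1.63e-05, and adjusted p = 0.0627 with an estimated correlation), with GARS1 at 94.3 ± 3.11 FPKM in siControl and 3.51-fold higher in siOXTR and WARS1 3.47-fold higher. Coat genes of transport vesicles between the endoplasmic reticulum and the Golgi were higher too: 7 of 8 coatomer (COPI) genes rose (median 0.71, adjusted p = 0.00255, and adjusted p = 0.0627 with an estimated correlation), with COPG2 (-0.59) lower, and 9 of 10 COPII genes rose (median 0.51, adjusted p = 0.00129, and adjusted p = 0.0627 with an estimated correlation), with SAR1B (-0.36) lower. Of 13 cytosolic chaperone genes, 11 rose and 1, BAG3 (-0.13), fell (median 0.57, adjusted p = 1.96e-04, and adjusted p = 0.0627 with an estimated correlation), among them HSPA8 (0.73) and HSPH1 (1.03). Of 17 targets of the oxidative stress factor NRF2, 15 rose and 2, NQO1 (-0.30) among them, fell (median 1.14, adjusted p = 1.63e-05, and adjusted p = 0.0544 with an estimated correlation). The heme oxygenase gene HMOX1 rose 8.61-fold from 24.9 ± 0.101 FPKM and the cystine transporter gene SLC7A11 7.14-fold.

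Of 17 genes of the actin cytoskeleton and its transcription factor SRF, 15 fell and 2, TPM4 (0.96) and TPM2 (0.36), rose (median -1.08, camera adjusted p = 1.96e-04, and adjusted p = 0.0544 with an estimated correlation). ACTB, often used as a reference gene, fell from 3860 ± 175 FPKM and was 2.66-fold lower in siOXTR, and VCL and FLNA had log2 changes of -1.69 and -1.28. Proteasome subunit genes rose in 18 of 31 cases and fell in 8 (median 0.14, adjusted p = 0.0418, and adjusted p = 0.403 with an estimated correlation). Genes of the ER membrane complex, which inserts membrane proteins, did not differ from the remaining genes as a list (2 of 8 rose and 5 fell, adjusted p = 0.277, and adjusted p = 0.444 with an estimated correlation), although EMC1 (-1.45) and EMC10 (-1.40) fell. No median of these groups changed sign under quantile or median-ratio scaling. The groups were picked because members stood out, so their p-values overstate the evidence.

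The first pattern weighed is the number of genes past the threshold. The 6 libraries can be split in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave 9613 genes, while the highest of the others gave 0 with limma (10 to 28 genes at an unadjusted p under 0.05). Each other split places libraries of both groups on each side, so the group difference itself widens the spread within a side. The 0 calls there therefore cannot decide whether the count arose by chance. Bias by transcript length or GC content and a shift of scale by a few abundant genes are argued against as the whole cause, since 9567 genes passed after the trend was removed and 9560 under median-ratio scaling. Direct repression through matches to ACTTTCA, the first word below, is argued against as the main source of decreases of at least 1 on the log2 scale. Of genes with such a decrease, 32.8% carried ACTTTCA or CTTTCAA in the 3' UTR against 22.3% of other genes, an excess of 10.5 percentage points (95% interval 7.16 to 13.9). The other genes include those that fell by less, and UTR length was not matched, so this comparison does not cover smaller decreases. Direct repression through a single seed of any sequence is argued against as the main source of the lower genes. Of 4096 cores of 6 bases, the one that accounts for the largest share of them, CTTTCA, accounts for 7.37% of 5118 (95% interval 4.60 to 10.1, and a highest upper limit over all cores of 11.4). The 4395 genes higher in siOXTR were not searched in this way. Whether a seed of the control siRNA accounts for those was therefore not tested and stays open. Of the 789 genes lower by at least 1, the core with the largest share was TTTTAT, with 14.7% (95% interval 5.25 to 24.1, and a highest upper limit over all cores of 24.2). Several seeds acting together, as from both strands of an siRNA or from a pool, were not tested and stay open. Also open is whether the changes follow from the loss of OXTR, from other effects of the siRNA, or from handling that differed between the groups, which 1 siOXTR arm against 1 siControl arm cannot separate.

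The second pattern is a link between short words in 3' UTRs and the change. Of 16144 words of 7 bases, ACTTTCA had the lowest score (1692 genes, mean adjusted log2 change -0.09, z = -5.53, permutation p over all words 0.0020), and CGGAGAA had the highest (241 genes, mean 0.20, z = 4.61, permutation p 0.0220). Base composition alone is weakly argued against: of 209 other words of the same bases, the lowest of the 208 without the core CTTTCA had z = -2.74. Since ACTTTCA was picked as the lowest of all words, none of these could score lower, and that choice may enlarge the gap. CTTTCAA (z = -4.76), which contains that core and overlaps ACTTTCA where both occur as ACTTTCAA, was left out of this test and meets neither bound, and the bound for this test (a gap of at least 2) replaced an earlier one (a score above -2.77, which -2.74 barely meets) after the value had been seen. Genes with the 8-base match ACTTTCAA lay lower than genes with only its 6-base core (difference -0.16, one-sided permutation p = 0.0001, the smallest possible) and than genes with a 7-base match (difference -0.11, p = 0.0005), and genes with TCGGAGAA lay higher than those with its core (difference 0.22, p = 0.0096) but not past the threshold against a 7-base match (difference 0.14, p = 0.0690), with words and tests taken from the same genes. A candidate explanation is seed-guided repression by the OXTR siRNA for ACTTTCA and by the control siRNA for CGGAGAA, which stays a hypothesis because the siRNA sequences are not given in the sources used here: ACTTTCA does occur once in the coding part of the OXTR transcript (bases 1454 to 1460 of 4364), but a transcript of this length has room for 26.6% of all such words, so the occurrence is weak evidence.

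The third pattern is a lower level of mRNAs whose proteins have a predicted signal peptide or membrane segment, first noticed in a list of the largest decreases longer than the 12 left out of its test. Without those 12, the median log2 change was -0.29 in 3109 such genes and 0.01 in 8476 others (difference -0.31, 95% interval -0.34 to -0.27, permutation p = 1e-05, the smallest possible), and 16.1% against 3.32% were lower by at least 1; the prediction took in 20 of 21 secreted or membrane members of the matrix list and 2 of 47 ribosomal proteins. Transcript length, GC content or level are argued against by a difference of -0.29 after regression, matches to ACTTTCA or CGGAGAA by -0.28 among genes with neither 6-base core, a single seed of any sequence by the smallest of the differences among genes lacking each of the 4096 cores in turn, -0.20 (95% interval -0.25 to -0.16), and the preset lists as its sole source by -0.30 among genes outside them. Whether translation at the endoplasmic reticulum is what these mRNAs have in common stays open, since the difference of -0.31 planned as its test is the pattern itself. Whether such mRNAs are made less or degraded faster was not tested, and the open explanations of the first pattern apply here too.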
